A study of Mus musculus with 3 samples.

How the data were processed

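The deposited files held whole-number UMI counts per gene and barcode for 3 inDrop libraries of live CD45+ cells from mouse hearts: wild-type infarct tissue 4 days after permanent coronary ligation, Irf3-/- infarct tissue at the same time, and left ventricular apex of a wild-type heart without infarct. Per the labels' protocols, cells were lysed in droplets and libraries were built by CEL-Seq and sequenced on an Illumina HiSeq instrument. Trimmomatic (version not given), Bowtie 1.1.1 and the GRCm38 build were named in the submitters' processing notes. The program that made the counts, the collapse of UMIs, the strand setting and the annotation were not given in the sources used here. The strain of the Irf3-/- mice and the deleted part of Irf3 were not given either. The count tables deposited by the authors listed 25040 genes and were not reduced to cells: 802, 385 and 2558 barcodes held under 100 UMIs. No symbol of a mitochondrial or ribosomal protein gene was among them, so the planned limit on mitochondrial UMIs removed nothing, and free RNA and damaged cells could be judged only from low barcodes, which were not tested for holding free RNA alone. The treatment text of the sample without infarct also names ligation; its condition and tissue labels were followed. Symbols had been altered by R naming and were restored, and 24843 gene IDs were placed on GRCm38 with GENCODE release M21. A separate list of gel barcodes was not used.

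Barcodes with at least 200 detected genes were kept as cells, 4224 of 10022. These held 89.2%, 97.1% and 90.6% of the UMIs of the wild-type infarct, Irf3-/- infarct and no-infarct libraries. Doublets were kept. Scrublet's method marked 16 of 4224 cells, 0.379%, and results without them are among the alternatives. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken without the interferon-stimulated list. After 30 principal components and 15 neighbours, Leiden clustering at resolution 1.0 gave 13 clusters (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9). No batch correction was applied, since library and group coincide. A cluster was called like the class with the most fixed markers detected in it at 2-fold or more, when these were at least 3. A cluster of low depth in every library, with no marker of its class among its 10 leading genes, would also have stayed unnamed. Clusters 0, 3 and 7 were named with 0 markers of their class among these 10. Cluster 12, with 15 cells and 2 markers, stayed unnamed. Marker lists covered monocyte/macrophage, neutrophil, dendritic, T, NK, B, mast and basophil, endothelial, fibroblast, mural, cardiomyocyte, erythroid, platelet and Schwann cells. Of the 7 erythroid markers 3 were in the files.

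UMIs were summed per library over kept cells and per class with at least 30 cells in each library compared, and given as CPM of the summed total. Comparisons were wild-type infarct over wild-type without infarct, and Irf3-/- infarct over wild-type infarct. With 1 library per group there was no replicate check, and no test between groups was made. Sums carry exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95% and all for counting error only. A fold against a library at 0 was set against a floor of 3 counts, and "at least" refers to this floor. The lower bound of the exact interval was lower, at 145 against 179 for Fcrls and 511 against 629 for Mgp in infarct over no infarct. Named genes were those with at least 50 UMIs over both libraries whose ratio interval lay farthest from 1 (7 per direction over all cells and in monocyte/macrophage-like cells, 4 per direction in neutrophil-like cells), leaving out Gm-number and Rik genes. The 3 members with the most UMIs of each list, Irf3 and Bcl2l12 were added, and of these the text gives those that describe each group. Gene lists were interferon-stimulated genes (56 of 57 in the files), interferon sensing and receptors, MHC class I, MHC class II, NF-κB inflammatory genes, monocyte chemokines, resident macrophage, inflammatory monocyte, repair, lipid and lysosome macrophage, glycolysis and hypoxia, proliferation, dissociation stress, and complement. Some genes were on more than 1 list: 5 of the resident macrophage genes, 6 of the repair, lipid and lysosome genes and 3 of the complement genes. A list's value is the median log2 ratio over members with at least 10 UMIs, with a pseudocount of 0.5 UMIs for members at 0 in 1 library. Its interval comes from 1000 Poisson draws of the counts, and its percentile from 10000 random lists matched on mean expression, as a description of these libraries. The interferon share of cells was the share with at least 5 list UMIs after each cell was thinned to 500 UMIs, a depth set by the tenth percentile of the shallowest library.

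Comparisons, gene lists, markers, filters, the rule for named genes and most alternatives were set before the data were examined. The alternatives were other cell filters, removal of doublets, other clustering resolutions, clustering with the interferon genes or on thinned cells, classes set per cell, other scalings, equal weight per cell, thinned cells, other member minimums and other thresholds. Alternatives without cluster 7, without members that share end sequence, and without cells holding mast cell genes were added after seeing the data. Sharing of end sequence was judged by common stretches of 40 bases in the last 500 bases of annotated transcripts: 2336 of 10693 genes and 15 of 82 named genes had one. The scripts were tested on simulated data, with independent Poisson counts drawn from the means of these libraries. This is the model behind the intervals, without clumping of UMIs in cells, correlated genes or differences between libraries. The test thus checks the calculation only. For infarct over no infarct, the median log2 ratio was 0.94 for 50 genes raised 2-fold, 1.96 for 50 raised 4-fold, −1.06 for 48 lowered 2-fold and −2.07 for 47 lowered 4-fold, and intervals held the truth for 93.6% to 96.0% of them. For Irf3-/- over wild-type infarct these medians were 1.02, 1.90, −1.00 and −2.02, with coverage of 89.8% to 98.0%. The 7 highest and 7 lowest genes were truly changed in both. Of 100 lists of unchanged genes, 0% and 3.00% lay outside the central 95% of random lists. Thinning was tested in 20 draws, which gave a mean share of 56.0% against 56.0% expected.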

Results

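Single cells from mouse hearts were profiled by inDrop, a droplet method that marks the 3′ end of each captured RNA with a cell barcode and a unique molecular identifier (UMI). Hearts of male mice were digested, and live cells with surface CD45, a protein of leukocytes, were sorted. The 3 libraries came from wild-type infarct tissue 4 days after permanent ligation of the left anterior descending coronary artery, from Irf3-/- infarct tissue at the same time, and from the left ventricular apex of a wild-type heart without infarct. The treatment text of this last sample also names ligation, so the absence of infarct rests on its condition and tissue labels. Each group had 1 library, so no difference below was tested against the spread between animals, and every interval (95%) covers counting error only. The wild-type infarct library held 3139896 UMIs in 3870 barcodes, the Irf3-/- infarct library 4297284 UMIs in 2564 barcodes, and the library without infarct 1495365 UMIs in 3588 barcodes. Barcodes with at least 200 detected genes were kept as cells: 1866, 1655 and 703, with median depths of 1365, 1737 and 1789 UMIs per cell, in that order.

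Irf3, the targeted gene (ENSMUSG00000003184; GRCm38 chromosome 7, 44997648 to 45002848, plus strand), was detected in every library. Over kept cells it had 81 UMIs in the wild-type infarct library, 78 in the Irf3-/- infarct library and 19 in the library without infarct. These were 28.9 (Poisson interval 23.0 to 36.0), 18.7 (14.8 to 23.3) and 14.0 (8.44 to 21.9) CPM, which scales a gene's UMIs to all UMIs of the same cells. The ratio of Irf3-/- to wild-type infarct was 0.646 (0.467 to 0.892) over all cells. It was 0.662 (0.454 to 0.965) in monocyte/macrophage-like cells and 1.00 (0.407 to 2.80) in neutrophil-like cells, where Irf3 had 20 and 7 UMIs. The deleted part of Irf3 was not given in the sources used here and the tags read 3′ ends, so these values do not check the genotype label. Bcl2l12, which overlaps the start of Irf3 on the minus strand (44991222 to 44998712), had 29, 17 and 2 UMIs. The ratio of Irf3-/- to wild-type infarct was 0.393 (0.203 to 0.740) for Bcl2l12. The overlap lies at the start of both genes, while the tags read 3′ ends, so it should hold few of them. Any reads there cannot be assigned with certainty, since the strand of counting was not given.

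Monocyte/macrophage-like and neutrophil-like cells made up most of each library. Monocyte/macrophage-like cells were 65.8% of kept cells in the wild-type infarct library (exact binomial interval 63.6 to 68.0), 49.4% in the Irf3-/- infarct library (47.0 to 51.9) and 30.2% in the library without infarct (26.8 to 33.7). Neutrophil-like cells were 21.3% (19.5 to 23.3), 40.6% (38.2 to 43.0) and 46.1% (42.4 to 49.9), in the same order. Dendritic-like cells were 10.6% (9.25 to 12.1), 4.53% (3.58 to 5.65) and 9.67% (7.59 to 12.1). T/NK-like cells were 1.501%, 1.75% and 5.69%, and B-like cells were 0.429%, 3.38% and 2.99%. Fibroblast-like cells were 31 of 703 in the library without infarct (4.41%), 1 in the wild-type infarct library and 2 in the Irf3-/- infarct library, although the gate selected CD45. These shares rest on sorted cells and on a gene minimum that shallow cells failed: 2004, 909 and 2885 barcodes were left out. With at least 500 genes per cell the neutrophil-like shares were 4.70%, 44.4% and 38.9%, without a filter 16.8%, 29.8% and 18.1%. When interferon-stimulated genes entered the clustering, the monocyte/macrophage-like share of the Irf3-/- library was 24.8%. Then 422 of the 493 cells of cluster 3, described below, were named for mast cells and basophils. Only 2 Irf3-/- cells held at least 5 UMIs of the mast cell genes Mcpt4, Cma1, Tpsb2 and Cpa3, so this lower share reflects naming.

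**Figure D1:**
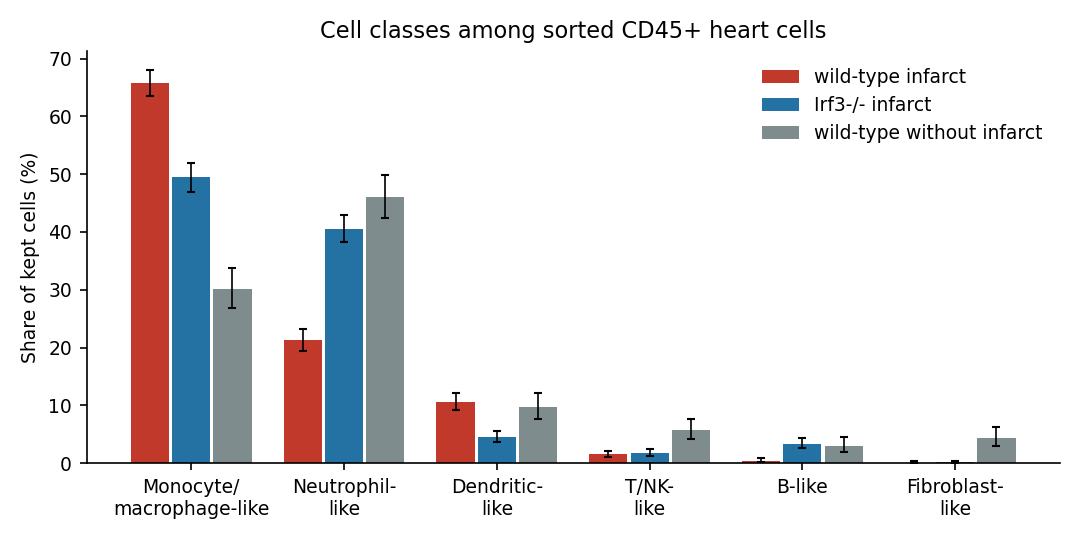
Share of kept cells (%) in each cell class, by library, with exact binomial 95% intervals as error bars. Monocyte/macrophage-like cells were 65.8% of the wild-type infarct library and 30.2% of the library without infarct, and neutrophil-like cells 21.3% and 46.1%.

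Different clusters filled the classes in the 3 libraries, so values within a class set unlike mixtures side by side, and a cluster mostly of 1 library may be that library. Among monocyte/macrophage-like cells, cluster 1, led by Ppbp, Ccl8 and Pdpn, held 43.7% in the wild-type infarct library. Cluster 3, led by cell-cycle genes such as Cdca8, Tk1 and Top2a, held 51.5% in the Irf3-/- infarct library, where its median depth was 5146 UMIs. It held 5.54% in the wild-type infarct library. Proliferation genes made up 0.544% of the class's UMIs in the Irf3-/- and 0.446% in the wild-type infarct, so its cells were not shown to be mostly in cycle. Cluster 5, led by Vcan, Plac8 and Chil3, held 68.9% in the library without infarct. Cluster 2, led by Apoe and Arg1, held 25.7%, 23.8% and 10.8%. Cluster 7 held 14.7%, 2.32% and 16.5%, and was led by Cfb, Ly6a, Axl and interferon-stimulated genes such as Ifit3, Cxcl10, Irf7 and Isg15. Among neutrophil-like cells, cluster 4, led by Csf1 and Siglecf, held 75.9% in the wild-type infarct library. Cluster 0, led by BC018473, Gpr84 and Il1a, held 88.7% in the Irf3-/- infarct library and 44.8% in the library without infarct. Cluster 8, led by Retnlg, held 15.6%, 2.98% and 23.5%. Median depths also differed, at 1619, 3240.5 and 2041 UMIs in monocyte/macrophage-like cells and 778, 1545 and 1724.5 in neutrophil-like cells.

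Markers of other cells were followed over all kept cells. Fibroblast markers had 1185.5 CPM in the wild-type infarct library, 1221 in the Irf3-/- infarct library and 6658 in the library without infarct. Monocyte/macrophage-like cells held 2169 of their 3319 UMIs in the wild-type and 3423 of 5097 in the Irf3-/- infarct, so these infarct values do not mark fibroblasts. Mural cell markers had 34.3, 23.7 and 808 CPM, endothelial markers 159, 143.5 and 341 CPM, and cardiomyocyte markers 28, 33 and 53 UMIs. Erythroid markers had 11.4, 12.7 and 317 CPM, and in barcodes under 100 UMIs, which were not sorted into free RNA, fragments and shallow cells, 20642 CPM without infarct and 0 in both infarct libraries. Platelet markers, with Ppbp among them, had 275, 19.9 and 6.64 CPM. Ppbp alone held 767 of their 769, 72 of 83 and 0 of 9 UMIs in the same order, so these values do not mark platelets. Mast and basophil markers had 9.64, 126.5 and 27.3 CPM, and Schwann cell markers 2.86, 3.11 and 4.43 CPM. T cell markers had 170, 131 and 553 CPM, NK cell markers 82.9, 80.5 and 317 CPM, and B cell markers 242, 489 and 669 CPM. In the wild-type infarct 374 of 678 B cell marker UMIs lay in monocyte/macrophage-like cells. Monocyte/macrophage markers had 41209, 27415 and 13919.7 CPM, neutrophil markers 5504.5, 7439.6 and 19580.4 CPM, and dendritic cell markers 436.5, 389 and 604 CPM.

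The wild-type infarct was compared with the wild-type heart without infarct to find which leukocytes and transcripts marked infarct tissue. The infarct library held a larger share of monocyte/macrophage-like cells, and these carried more RNA of Apoe, complement C1q and lysosomal cathepsins and less of inflammatory monocyte genes. Most interferon-stimulated genes had higher summed levels in monocyte/macrophage-like, neutrophil-like and dendritic-like cells. The largest excess over all cells was in Fcrls, a macrophage Fc receptor-like gene (chromosome 3, 87250758 to 87263738), with 1109 UMIs against 0, at least 179-fold higher. In every fold against 0, "at least" refers to a floor of 3 counts and not to the exact interval, whose lower bound was 145 for Fcrls. The largest deficit was in Mgp, a matrix protein gene (chromosome 6, 136872435 to 136875823), with 0 UMIs against 914, at least 629-fold lower. Of these UMIs 903 lay in the 31 fibroblast-like cells, so this deficit lay mainly outside the leukocyte-like classes.

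Among the other top-ranked genes over all cells, Ppbp had 767 UMIs against 0 (at least 124-fold higher). Pf4, the platelet factor 4 chemokine also made by macrophages (chromosome 5, 90772435 to 90773383), was 115-fold higher (80.7 to 169), and Apoe, the lipid carrier apolipoprotein E (chromosome 7, 19696109 to 19699188), 38.9-fold higher (34.9 to 43.4). The monocyte-attracting chemokines Ccl12 and Ccl8 had ratios of 70.9 (27.6 to 261) and 97.3 (26.8 to 806), the latter from 402 against 2 UMIs. Cxcl1, which attracts neutrophils, was 33.8-fold higher (22.2 to 54.0). On the lower side, the collagen gene Col5a2 had 1 UMI against 240, a ratio of 0.00202 (5.08e-05 to 0.0114), and the proteoglycan gene Bgn, which shares end sequence with 72 other genes, was 126-fold lower (77.0 to 221). The microfibril genes Fbn1 and Mfap5 were at least 82.6-fold and 77.8-fold lower, from 0 UMIs. Fibroblast-like cells held all Col5a2 and Mfap5 UMIs without infarct, 97.9% of Bgn and 95.8% of Fbn1, and 445 of the 914 Mgp UMIs lay in 3 cells. Alas2, the erythroid heme synthesis enzyme, was at least 158-fold lower, with 230 UMIs in 36 cells and 12858 CPM in low barcodes of the library without infarct. BC018473, annotated as antisense, had 9 UMIs against 990 and is uncertain because the strand of counting was not given.

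Within monocyte/macrophage-like cells Cxcl1 (1317 UMIs against 0), Fcrls, Ppbp and Ccl8 were at least 92.1-fold, 76.2-fold, 52.9-fold and 27.8-fold higher, and Pdpn, the membrane glycoprotein podoplanin, at least 25.7-fold. Pf4 was 50.7-fold (35.5 to 75.2) and Apoe 17.5-fold higher (15.6 to 19.6). Chil3, a chitinase-like protein of monocytes, was 13.5-fold lower (11.7 to 15.5) and the transcriptional repressor Hes1 14.6-fold lower (9.76 to 22.3). Arg2, the mitochondrial arginase, was 10.6-fold lower (7.48 to 15.4), Atf5 9.72-fold (5.97 to 16.2) and the integrin gene Itgb7 8.17-fold (5.30 to 12.8). Saa3, an acute-phase gene, was 9.94-fold lower (7.74 to 12.8), but 177 of its 204 UMIs without infarct lay in 3 cells, and it shares end sequence with 164 other genes. Lilra6 was 10.1-fold lower (5.44 to 19.7) and shares end sequence with 3 other genes. In barcodes under 100 UMIs without infarct Atf5, Arg2 and Lilra6 had 591, 153 and 95.4 CPM, beside 121, 240.1 and 77.8 CPM in these cells, and in those of the infarct library 0, 59.1 and 0 CPM. Cxcl1 and Ppbp had 650 and 433 CPM in low barcodes of the infarct library, beside 632 and 363 CPM in the cells. In neutrophil-like cells of the infarct Apoe, C1qb and Pf4 had 1022, 156 and 96.8 CPM, beside 8350.4, 2363 and 1694 CPM in low barcodes. If low barcodes held free RNA and both classes took it up alike, such RNA was a small part of the cells. That argues against background as the main source of Cxcl1, which stood near its low-barcode level. For Ppbp background is argued against by 0 UMIs of platelet markers, Ppbp among them, in neutrophil-like cells of the infarct. Without infarct, erythroid markers had 20642 CPM in low barcodes and 68.6 CPM in monocyte/macrophage-like cells. If those barcodes held free RNA, this argues against background as the main source of Atf5, Arg2 and Lilra6 there.

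Macrophage gene groups were higher in monocyte/macrophage-like cells of the infarct, and inflammatory monocyte genes lower. Without infarct 68.9% of these cells lay in the Vcan-led cluster 5, and blood carried in with the tissue was not excluded for that library. Of 21 repair, lipid and lysosome genes, 20 were higher (median log2 ratio 1.60, interval 1.52 to 1.73; percentile 100 among 10000 matched random lists), with Ctsb 3.11-fold (2.94 to 3.28) and Ctsd 3.04-fold (2.84 to 3.25). Of 9 complement genes, 8 were higher (median 1.09), with C1qa 9.88-fold (8.11 to 12.2) and C1qb 6.16-fold (5.48 to 6.94). Resident macrophage genes had a median of 1.08, with 12 of 18 higher, among them Mrc1, the mannose receptor, at 12.7-fold (9.37 to 17.5). Monocyte chemokines had a median of 1.29, with 8 of 12 higher, although Ccl6 was 1.42-fold lower (1.31 to 1.54). All 13 inflammatory monocyte genes were lower (median −1.65, interval −1.80 to −1.51; percentile 0), with the matrix protein Thbs1 4.63-fold (4.36 to 4.92) and the calcium-binding S100a6 1.86-fold lower. Proliferation genes had a median of 1.53, with 15 of 20 higher, but 0.85 with genes at 0 UMIs placed at the floor of 3 counts. MHC class II genes, which present antigen to CD4 T cells, had a median of −0.74, with 7 of 8 lower and Cd74 1.86-fold lower (1.76 to 1.97). Il1b, the interleukin 1β gene, was 4.74-fold lower (4.53 to 4.95).

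Most interferon-stimulated genes, which interferons induce against viruses, had higher summed levels in the infarct in each class examined. Over all cells 51 of 56 were higher (median log2 ratio 1.28, interval 1.16 to 1.51; percentile 100), and 35 at least 2-fold. In monocyte/macrophage-like cells 46 of 56 were higher (median 1.01, 0.93 with genes at 0 placed at the floor), in neutrophil-like cells 42 of 44 (1.49) and in dendritic-like cells 39 of 43 (1.62, or 1.42 at the floor). Isg15, a ubiquitin-like protein (chromosome 4, 156199424 to 156200818), was 3.26-fold (2.52 to 4.30), 3.94-fold (2.94 to 5.34) and 14.6-fold higher (6.58 to 40.5) in these classes. Ly6e, the member with the most UMIs, was 1.73-fold lower (1.59 to 1.89) in monocyte/macrophage-like cells, where the list's summed UMIs had a log2 ratio of 0.41. The list made up 0.743% of UMIs in the infarct and 0.398% without infarct, beside 0.754% and 0.492% in barcodes under 100 UMIs, so the list was also present in these. Genes that sense or receive interferon had medians of 0.29 over all cells (13 of 18 higher), −0.04 in monocyte/macrophage-like cells and 0.10 in neutrophil-like cells.

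Neutrophil-like cells of the infarct carried Cxcl1 at 173 UMIs against 0, at least 89.0-fold higher. Apoe (380 UMIs against 3) had a ratio of 196 (66.4 to 953), C1qb (58 against 1) a ratio of 89.5 (15.4 to 3597), and H2-Eb1, an MHC class II gene, was 14.2-fold higher (8.32 to 26.1). In barcodes under 100 UMIs these 4 genes had 650, 8350.4, 2363 and 4274 CPM in the infarct library. Without infarct they had 19.1, 134, 248 and 3739 CPM there. In neutrophil-like cells of the infarct they had 465, 1022, 156 and 371 CPM. Apoe, C1qb and H2-Eb1 thus lie beside a high background. If low barcodes held free RNA, these genes limit its part in the cells, which argues against it as the main source of Cxcl1. MHC class II genes had a median of 2.98 in these cells (6 of 6 measured members higher), resident macrophage genes 2.43 (7 of 7) and complement genes 3.51 (7 of 8; 2.18 at the floor), against the same background. Their summed UMIs had log2 ratios of 2.42, 0.98 and 0.50. MHC class I genes had a median of 0.72 (9 of 10; summed UMIs 0.18), repair, lipid and lysosome genes 0.71 (11 of 15) and NF-κB inflammatory genes 0.40 (14 of 23). On the lower side, BC018473 had 2 UMIs against 931, and Alas2 was at least 41.5-fold lower, from 0 UMIs, at 334 CPM without infarct beside 12858 CPM in low barcodes. Rmnd5a had 1 UMI against 75, a ratio of 0.0206 (5.14e-04 to 0.118), at 131 CPM without infarct beside 209.9 CPM in low barcodes.

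The remaining groups differed less, or differently by cell set. Over all cells NF-κB inflammatory genes had a median of −0.49 (19 of 24 lower), with Il1b 3.69-fold lower (3.61 to 3.77) and Nfkbia, the NF-κB inhibitor, 1.62-fold lower (1.59 to 1.65). In monocyte/macrophage-like cells that median was −0.09, while the mean was 0.11. Over all cells all 11 MHC class I genes were higher (median 0.54), though B2m turned below 0 with thinned cells or with cells weighted equally, and the median was 0.21 in monocyte/macrophage-like cells. Over all cells the medians were 2.06 for repair, lipid and lysosome genes and for monocyte chemokines, 1.63 for complement, 0.97 for proliferation, 0.60 for resident macrophage genes (summed UMIs 2.68), 0.29 for MHC class II and −0.92 for inflammatory monocyte genes. Glycolysis and hypoxia genes had medians of 0.12 over all cells (mean −0.09), −0.01 in monocyte/macrophage-like and −0.30 in neutrophil-like cells. Dissociation stress genes had medians of −0.30, −0.34 and 0.02. In neutrophil-like cells the medians were −0.17 for 5 monocyte chemokines (summed UMIs 0.18), −0.26 for inflammatory monocyte genes and −0.47 for 9 proliferation genes. Median-of-ratios scaling moved every log2 ratio of this comparison by 0.10 over all cells, 0.20 in monocyte/macrophage-like, 0.16 in dendritic-like and −0.03 in neutrophil-like cells; the medians of −0.04, −0.09 and −0.01 in monocyte/macrophage-like cells and of 0.02 in neutrophil-like cells change sign under it.

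**Figure D2:**
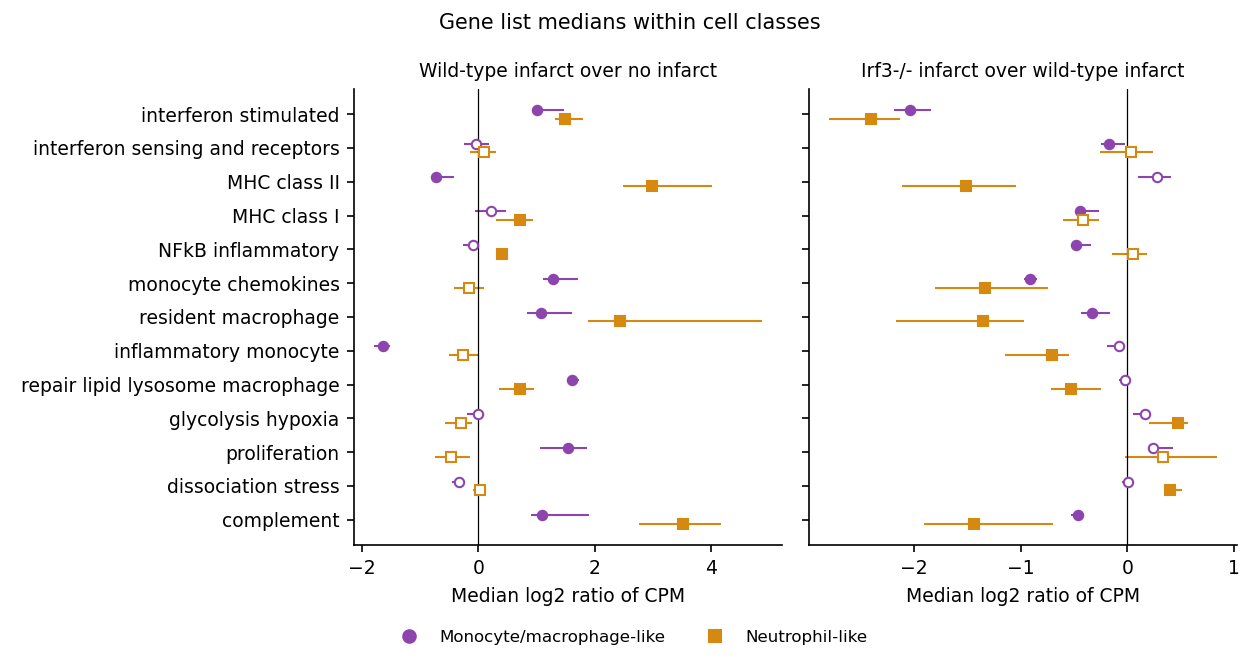
Median log2 ratio of CPM for each gene list in monocyte/macrophage-like (circles) and neutrophil-like cells (squares), with 95% intervals from Poisson resampling of the counts; filled symbols lie outside the central 95% of matched random lists. Interferon-stimulated genes had medians of 1.01 and 1.49 in wild-type infarct over no infarct and of −2.04 and −2.41 in Irf3-/- over wild-type infarct. Both comparisons use the same wild-type infarct library.

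The Irf3-/- infarct was compared with the wild-type infarct to find which transcripts differed without this transcription factor, which activates type I interferon genes. Interferon-stimulated genes were lower in the Irf3-/- library in every class examined. Apoe was also lower, by 8.399-fold (8.13 to 8.68) in monocyte/macrophage-like cells. Neutrophil-like cells were a larger share of the Irf3-/- library, 40.6% against 21.3%, and monocyte/macrophage-like cells a smaller share, 49.4% against 65.8%. The libraries also differed in depth and in the clusters that filled each class, and genotype and library cannot be separated.

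All 56 interferon-stimulated genes measured over all cells were lower in the Irf3-/- library, 47 of them at least 2-fold (median log2 ratio −2.00, interval −2.18 to −1.89; percentile 0 among 10000 matched random lists, whose central 95% ran from −0.06 to 0.21). All 56 were also lower in monocyte/macrophage-like cells (median −2.04, interval −2.19 to −1.84), though Ly6e turned above 0 with thinned cells. All 44 measured in neutrophil-like cells were lower (median −2.41, interval −2.80 to −2.13), as were 40 of 44 in dendritic-like cells (−2.41, or −1.94 with genes at 0 placed at the floor). The list's summed UMIs had log2 ratios of −1.53, −1.49, −1.62 and −1.33 in these 4 sets, smaller in size than the medians. The list made up 0.257% of UMIs in the Irf3-/- library against 0.743%, and 0.233% against 0.754% in barcodes under 100 UMIs.

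Antiviral effectors were among the lowest-ranked genes. Ifit2, which binds viral RNA (chromosome 19, 34550694 to 34576419), had 7 UMIs against 258, 54.9-fold lower (26.3 to 138). Rsad2, the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), was 29.0-fold lower over all cells (19.4 to 45.2), 30.9-fold in monocyte/macrophage-like (18.8 to 54.7) and 28.2-fold in neutrophil-like cells (14.2 to 63.7). Ifit3 had 2 UMIs against 288, a ratio of 0.00466 (5.61e-04 to 0.0170), and the dynamin-like GTPase gene Mx1 3 against 174, a ratio of 0.0116 (0.00236 to 0.0344). Both share end sequence with a neighbour, Ifit3b and Mx2, so reads may be split between copies. In monocyte/macrophage-like cells Oasl1 had 3 UMIs against 129, a ratio of 0.0173 (0.00353 to 0.0518), and Ifit1bl1 was at least 25.5-fold lower, from 0 UMIs against 57. In neutrophil-like cells Oasl2, which shares end sequence with 15 other genes, was 32.8-fold lower (12.0 to 125.5) and Rtp4 14.7-fold (8.04 to 29.0). Barcodes under 100 UMIs of the wild-type infarct held Rsad2, Oasl2, Mx1 and Ifit3 at 276, 197, 78.8 and 78.8 CPM, beside 239, 124, 62.2 and 103 CPM in the cells (the first 2 in neutrophil-like, the last 2 in all), and those of the Irf3-/- infarct held 0, where 3 counts would be 111 CPM. Bst2, the tetherin gene, was 2.82-fold lower (2.55 to 3.13) in monocyte/macrophage-like cells, and the Fc receptor gene Fcgr1 1.70-fold (1.55 to 1.86). Pdpn, which is not on the list, was 34.6-fold lower over all cells (21.01 to 61.1). Pydc4, which shares end sequence with Pydc3, and Spon1 were at least 32.3-fold and 28.3-fold lower, from 0 UMIs.

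Cells with a strong interferon signature were fewer in the Irf3-/- library after each cell was thinned to 500 UMIs. At least 5 list UMIs were found in 28.3% of wild-type infarct (25.7 to 30.9), 6.25% of Irf3-/- infarct (4.595 to 8.27) and 21.9% of no-infarct monocyte/macrophage-like cells (16.5 to 28.1). In neutrophil-like cells the shares were 18.7% (14.9 to 23.0), 3.17% (1.97 to 4.81) and 8.70% (5.86 to 12.3). In dendritic-like cells they were 28.7% (22.5 to 35.6), 0 of 68 (0 to 5.28) and 4.41% (0.919 to 12.4). Over all cells they were 26.4%, 4.97% and 14.0%. Unthinned shares were 64.7%, 61.7% and 71.2% in monocyte/macrophage-like cells and 29.7%, 23.4% and 36.4% in neutrophil-like cells. Without Ly6e, Bst2 and Fcgr1, the list members with the most UMIs, the thinned monocyte/macrophage-like shares were 19.0%, 1.53% and 10%. Thinning left out 46, 98 and 2 monocyte/macrophage-like cells and 18, 10 and 2 neutrophil-like cells, and 211, 76 and 41 of the former lay within 1 UMI of the threshold.

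**Figure D3:**
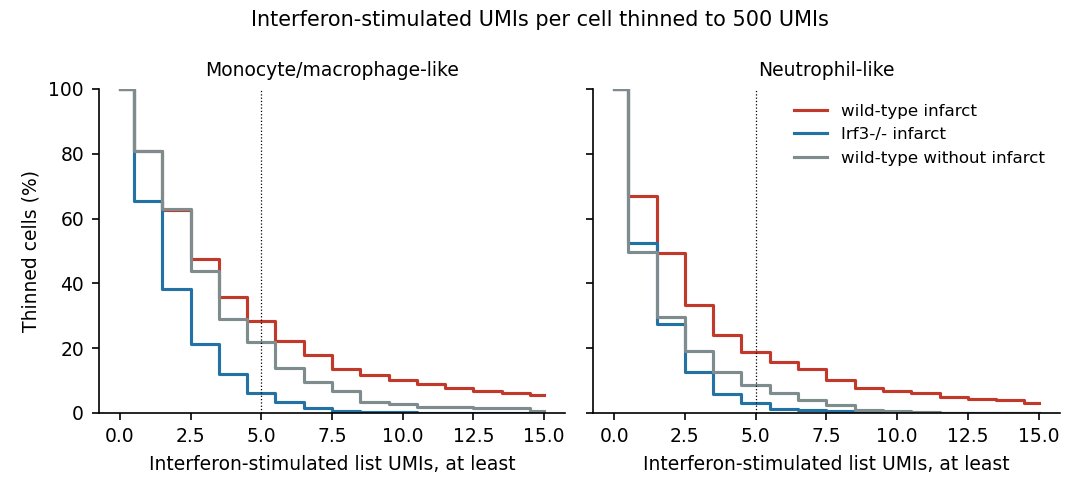
Share of cells (%) thinned to 500 UMIs that hold at least the number of interferon-stimulated UMIs on the x axis, for monocyte/macrophage-like and neutrophil-like cells of each library; the dotted line marks 5 UMIs. At that threshold the monocyte/macrophage-like shares were 28.3% in the wild-type infarct, 6.25% in the Irf3-/- infarct and 21.9% without infarct.

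Other macrophage transcripts differed between the infarct libraries as well. In monocyte/macrophage-like cells Apoe had 1497.5 CPM in the Irf3-/- library against 12578 in the wild type, and 2443.5 against 8350.4 CPM in barcodes under 100 UMIs. Over all cells it was 9.42-fold lower (9.12 to 9.73). Monocyte chemokines had a median of −0.91 in monocyte/macrophage-like cells, with 11 of 12 lower, among them Pf4 at 2.21-fold (2.13 to 2.29). Resident macrophage genes had a median of −0.33 (11 of 17 lower), with Mrc1 2.09-fold lower (1.97 to 2.23), and complement genes −0.46 (7 of 9), with C1qb 1.43-fold lower (1.39 to 1.48). NF-κB inflammatory genes had a median of −0.48 (21 of 24 lower; percentile 0) and MHC class I genes −0.44 (10 of 11), with H2-K1 1.495-fold lower (1.43 to 1.57). H2-K1 and H2-D1 share end sequence, so their split is uncertain. MHC class II genes had a median of 0.28 (5 of 8 higher), with Cd74 1.28-fold higher (1.23 to 1.33). Repair, lipid and lysosome genes had a median of −0.02, while their summed UMIs, to which Apoe contributes, had a log2 ratio of −0.40.

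Genes of higher level in the Irf3-/- library included transcripts of few cells. Mcpt4, Cma1, Tpsb2 and Cpa3, proteases of mast cells, had 183, 121, 118 and 73 UMIs against 0, at least 40.9-fold, 27.1-fold, 26.4-fold and 16.3-fold higher. Of their 495 UMIs, 457 lay in 1 cell. Ctsk, the cysteine protease cathepsin K, was 18.3-fold higher (12.1 to 29.1), but 356 of its 628 UMIs lay in 3 of 36 cells. In monocyte/macrophage-like cells its log2 ratio turned to −0.87 with at least 500 genes per cell. Card9, a signalling adaptor of fungal receptors (chromosome 2, 26352176 to 26360918), was 20.9-fold higher (11.2 to 43.9), with 311 UMIs in 185 cells against 10 in 8 cells, and had 75 UMIs in the library without infarct. BC018473 (chromosome 11, 116752167 to 116759373) was 254-fold higher (134 to 557), again with the strand of counting not given. It shares end sequence with Tfcp2, named for this reason only, which had 22 UMIs in the Irf3-/- and 11 in the wild-type infarct library. In neutrophil-like cells Hnrnph3, an RNA-binding protein gene, had 102 UMIs against 1, a ratio of 35.7 (6.27 to 1425.5), and the chaperone gene Hsph1 was at least 6.19-fold higher, from 53 UMIs against 0. Apoe was 49.3-fold lower (32.1 to 79.6) in these cells, at 20.7 against 1022 CPM, beside 2443.5 against 8350.4 CPM in barcodes under 100 UMIs.

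The remaining groups differed by cell set between the infarct libraries. Over all cells NF-κB inflammatory genes had a median of 0.38 (19 of 24 higher), with Il1b 2.05-fold higher (2.01 to 2.09), but the Il1b ratio was 0.986 (0.947 to 1.03) in monocyte/macrophage-like cells and the list median 0.05 in neutrophil-like cells (mean −0.05). Dissociation stress genes had medians of 0.47 over all cells (15 of 18 higher), 0.01 in monocyte/macrophage-like and 0.40 in neutrophil-like cells. Glycolysis and hypoxia genes had medians of 0.14, 0.17 and 0.48, the last with 19 of 24 higher, and proliferation genes 0.01, 0.24 and 0.34. Inflammatory monocyte genes had medians of −0.24, −0.08 and −0.70. Genes that sense or receive interferon had medians of −0.15, −0.17 and 0.03, the middle value turned to 0.19 with thinned cells, and summed UMIs in neutrophil-like cells had a log2 ratio of −0.36. Over all cells the medians were −0.71 for monocyte chemokines, −0.62 for complement, −0.52 for resident macrophage genes, −0.45 for MHC class I, −0.44 for MHC class II and −0.18 for repair, lipid and lysosome genes. In neutrophil-like cells they were −1.33, −1.44, −1.35, −0.42, −1.51 and −0.53 in that order, beside macrophage RNA in low barcodes; the summed complement UMIs had a log2 ratio of −0.08. Median-of-ratios scaling moved every log2 ratio by −0.06 over all and in monocyte/macrophage-like cells and by 0.10 in neutrophil-like cells, and the medians of 0.01 change sign under it.

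Gm8797, chosen after its values were seen, was nearly absent from the wild-type infarct library. It had 71 UMIs there, 7727 in the Irf3-/- infarct library and 2730 without infarct. Its near-identical partner Ubb, a polyubiquitin gene, had 4327, 1080 and 545 UMIs. The pair together had 1571 CPM in the wild-type infarct, 2109.9 in the Irf3-/- infarct and 2417 without infarct, and 1.61% (1.26 to 2.03), 87.7% (87.0 to 88.4) and 83.4% (82.0 to 84.6) of its UMIs were counted on Gm8797. The 2 genes share 237 stretches of 40 bases in their transcript ends, so single values of either are uncertain.

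**Figure D4:**
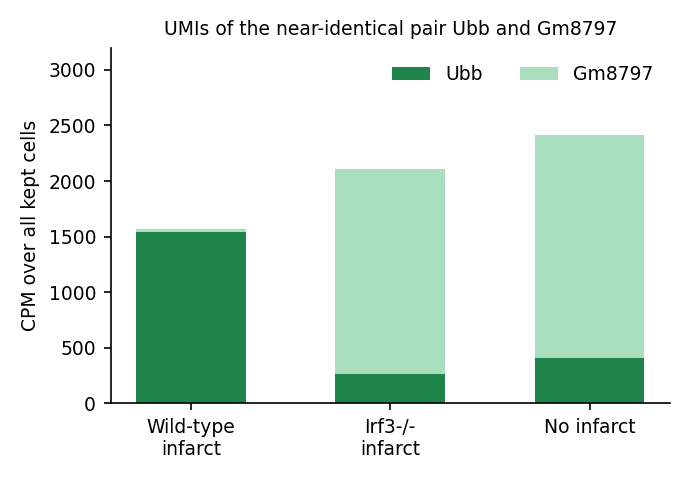
CPM of Ubb and Gm8797 stacked for each library, over all kept cells. The stacks reach 1571, 2109.9 and 2417 CPM, and the part on Gm8797 was 1.61%, 87.7% and 83.4%.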

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

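The test of interferon-stimulated genes by cluster and all tests on Gm8797, BC018473 and Card9 and on the neutrophil-like cells without infarct were chosen after the result was seen. MHC class II genes drew attention because they lay on opposite sides of 0 in the classes of the wild-type comparison. Their median log2 ratio of infarct over no infarct was −0.74 in monocyte/macrophage-like cells and 2.98 in neutrophil-like cells, a difference of −3.72 that was not tested. H2-Eb1 in barcodes under 100 UMIs had 4274 CPM with infarct and 3739 without, against 371 and 26.1 CPM in neutrophil-like cells.

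Interferon-stimulated genes were lower in the Irf3-/- infarct library than in the wild-type infarct library. A different mix of clusters as the whole cause is argued against by the medians inside 7 clusters with at least 30 cells in both libraries, which ran from −3.05 to −1.03. Cluster 7, with 19 Irf3-/- cells, was too small for this. It held 14.7% of wild-type and 2.32% of Irf3-/- infarct monocyte/macrophage-like cells. Without it the median of this class was −1.71 instead of −2.04, so the mix may account for a part. Reads shared between near-identical genes are argued against by a median of −1.98 over 35 members without shared end sequence. With barcodes under 100 UMIs taken as free RNA, which was not tested, free RNA alone in neutrophil-like cells is argued against by their list UMIs per Apoe UMI in the wild-type infarct, 6.80 times those of such barcodes (6.10 to 7.60). Loss of Irf3 may account for the difference, as a hypothesis only, since genotype and library coincide and a difference between single hearts or preparations stays open. The excess with infarct adds no separate evidence, because it rests on the same wild-type infarct library. Over all kept cells the list made up 0.257% of UMIs in the Irf3-/- infarct and 0.398% without infarct.

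Gm8797, BC018473 and Card9 were nearly absent from the wild-type infarct library and present in both others. A different mix of cell classes is argued against: the lowest lower bound of the ratio of Irf3-/- to wild-type infarct was 6.46 over these 3 genes in monocyte/macrophage-like and neutrophil-like cells. For Gm8797, assignment of shared reads to Ubb fits, since the pair summed to a ratio of 1.34 while 1.61% and 87.7% of its UMIs lay on Gm8797. This could mean that the libraries were aligned or counted differently, which the pair alone does not show for Card9 or for BC018473, whose partner in shared end sequence, Tfcp2, had 11 UMIs in the wild-type infarct library. A variant in the mice of the wild-type infarct stays open and untested, and genotype does not separate this library from the wild type without infarct. Other genes were lowest in the wild-type infarct as well and were not tested. Gm43549 had 6.79 CPM there, 47.0 in the Irf3-/- infarct and 35.4 without infarct. Cygb had 0, 54 and 54 UMIs in the same order, with 38 and 33 of the latter in 3 cells.

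Neutrophil-like cells were 46.1% of the library without infarct. Barcodes exchanged with the infarct libraries are argued against: 15 of 324 of these cells, 4.63% (2.61 to 7.52), carried a barcode also present there, against 22 of 379 other cells, 5.80% (3.67 to 8.66). Blood carried in with the tissue could not be excluded or shown, with Alas2 at 12858 CPM in its barcodes under 100 UMIs and 0 in those of the infarct libraries (floors of 59.1 and 111 CPM). What keeps it open is that only 23.5% of these neutrophil-like cells lay in the Retnlg-led cluster 8, and that the red cell RNA does not tell where neutrophils came from. A response of the heart tissue itself was not tested. Of the monocyte/macrophage-like cells without infarct, 68.9% lay in the Vcan-led cluster 5. Fcrls, Pf4, Mrc1, C1qa and C1qb had a UMI in 0, 12, 18, 22 and 43 of its 703 kept cells. Blood thus stays open for these cells too, and bears on every macrophage gene found higher in the infarct.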

How the results depend on the processing

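Alternatives without cluster 7, without members that share end sequence and without cells holding mast cell genes were chosen after the result was seen; all others were planned. Over the alternatives run, the interferon-stimulated median kept its sign in both comparisons: −2.17 to −1.53 over all cells, −2.20 to −1.49 in monocyte/macrophage-like and −2.73 to −1.62 in neutrophil-like cells for Irf3-/- over wild-type infarct, and 0.90 to 1.39, 0.41 to 1.35 and 1.103 to 1.98 for infarct over no infarct. Of these values 60 lay within the counting interval and 14 outside it. The ratio of summed list UMIs gave 0.90, 0.41 and 1.103 for infarct over no infarct and −1.53, −1.49 and −1.62 for Irf3-/- over wild type, a measure in which members with many UMIs weigh most. Without cluster 7 the monocyte/macrophage-like medians were 0.83 and −1.71. With at least 500 genes per cell the neutrophil-like infarct median was 1.98 and the monocyte/macrophage-like Irf3-/- median −1.81, which was −2.20 with thinned cells. With members of at least 50 UMIs the neutrophil-like medians were 1.22 and −1.79, and equal weight per cell gave 1.30 for the former. Shares of monocyte/macrophage-like cells in the wild-type infarct, Irf3-/- infarct and no-infarct libraries were 33.3%, 31.5% and 7.87% without a cell filter, 79.7%, 40.9% and 38.4% with at least 500 genes, 58.2%, 32.6% and 19.5% with classes set per cell, and 57.2%, 35.9% and 26.2% with clustering on thinned cells. At resolution 2.0 they were 63.0% and 44.6% in the infarct libraries. With interferon-stimulated genes in the clustering the Irf3-/- share was 24.8%. Of the 493 cells of cluster 3, 422 then fell in clusters named for mast cell and basophil markers. Only 2 Irf3-/- cells held at least 5 UMIs of Mcpt4, Cma1, Tpsb2 and Cpa3, so this lower share reflects naming. Neutrophil-like shares were 16.8%, 29.8% and 18.1% without a filter, 4.70%, 44.4% and 38.9% with at least 500 genes, and 16.8%, 23.4% and 34.3% with classes set per cell; clustering on thinned cells gave 43.6% in the Irf3-/- library. In all these settings the wild-type infarct had the highest monocyte/macrophage-like and the lowest neutrophil-like share, while the order of the other libraries in neutrophil-like share varied. Without a filter no dendritic-like or B-like class formed. The other 23 shares of these classes lay within their counting intervals, as did 50 of 66 shares of the remaining classes. Shares of thinned monocyte/macrophage-like cells at the interferon threshold were 47.4%, 21.2% and 43.8% at 3 UMIs, 10.2%, 0.278% and 2.86% at 10 UMIs, 51.1%, 22.6% and 50.5% with cells thinned to 1000 UMIs, and 19.0%, 1.53% and 10% without the 3 most abundant members. Without cluster 7 the wild-type infarct share was 24.8%. In neutrophil-like cells they were 33.4%, 12.5% and 18.9% at 3 UMIs, 6.84%, 0.151% and 0.621% at 10 UMIs and 40%, 11.0% and 21.4% at 1000 UMIs, and 1.96% in the Irf3-/- library without those members. The Irf3-/- share was the lowest wherever 3 shares are given. The sensing median for Irf3-/- in monocyte/macrophage-like cells turned to 0.19 with thinned cells; of the other list medians 588 lay within the counting interval, 21 of them on the other side of 0, and 200 outside it, 30 of them on the other side. Of single-gene values 1213 lay within the counting interval, 16 of them on the other side of 0, and 426 outside it, also with 16 on the other side; 30 more changed sign where the reported interval excluded a ratio of 1. Thinned cells gave log2 ratios of infarct over no infarct over all cells of 0.29 for Irf1, 0.018 for Cd74, −0.0052 for B2m and 0.050 for Fn1, which like Gapdh shares end sequence with other genes. In the Irf3-/- comparison they gave 0.011 for Ly6e, 0.21 for Irf1, 0.027 for Cxcl2, 0.0079 for Dusp1 and 0.45 for Bcl2l12 in monocyte/macrophage-like cells, and −0.28 for Ctsd and −0.10 for Gapdh over all cells. Equal weight per cell gave 0.19 for Irf1, −0.064 for B2m and 0.079 for Fn1 over all cells and −0.013 for Bst2 in neutrophil-like cells of the former comparison. In the latter it gave 0.017 for Irf1, 0.0031 for Cxcl2 and 0.056 for Dusp1 in monocyte/macrophage-like cells and −0.23 for Ctsd and −0.089 for Gapdh over all cells. At least 500 genes per cell gave −0.045 for H2-Eb1 over all cells and 0.015 for Cxcl2 in monocyte/macrophage-like cells with infarct, and for Irf3-/- 0.039 for Fn1, −0.026 for H2afz and −0.87 for Ctsk in monocyte/macrophage-like cells and −0.086 for Ctsd over all cells. Without a filter Cxcl2 had 0.25 with infarct and Fn1 0.024 for Irf3-/- in monocyte/macrophage-like cells. Median-of-ratios scaling gave 0.13 for Cxcl2 in monocyte/macrophage-like cells with infarct and −0.018 for Gapdh over all cells for Irf3-/-. The cause was not tested. Depth limits genes of few UMIs, such as Irf3 with 19 UMIs without infarct.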

Other observations

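The test on genes near Irf3 was chosen after the result was seen. Interferon-stimulated genes also differed inside single clusters of the wild-type libraries. Their median log2 ratio of infarct over no infarct was 2.36 in cluster 7 (47 of 50 members higher), 2.04 in the BC018473-led cluster 0 and 1.81 in the Csf1-led cluster 4. It was 1.23 in the Vcan-led cluster 5 and 0.91 in the Retnlg-led cluster 8. In the wild-type infarct the list made up 1.42% of UMIs in cluster 7, 1.01% in cluster 5, 0.624% in cluster 1 and 0.415% in cluster 3. In the Irf3-/- infarct it made up 0.542% in cluster 5 and 0.235% in cluster 3. Among lymphocytes thinned to 500 UMIs, at least 5 list UMIs were found in 7 of 20 T/NK-like cells of the wild-type infarct, 4 of 28 of the Irf3-/- infarct and 12 of 40 without infarct. In B-like cells the numbers were 2 of 7, 5 of 47 and 5 of 20.

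Single genes chosen after their values were seen also differed in how cells carried them. Siglecf, a lectin of eosinophils and of some neutrophils, had 111 CPM in 101 cells of the wild-type infarct, 144 CPM in 220 cells of the Irf3-/- infarct and 263 CPM in 81 cells without infarct. Acp5, the tartrate-resistant acid phosphatase of osteoclasts and some macrophages, had 101, 250.1 and 50.2 CPM, with 292 of 1044 Irf3-/- UMIs in 3 cells. Barcodes left out by the gene minimum carried interferon-stimulated genes at 0.750% of UMIs in the wild-type infarct (0.722 to 0.780), 0.244% in the Irf3-/- infarct (0.217 to 0.273) and 0.844% without infarct (0.797 to 0.894). The order of the wild-type libraries was thus opposite to that of kept cells, 0.743% and 0.398%, while the Irf3-/- library was lowest in both.

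A passenger region around the targeted allele is a candidate explanation for differences of genes near Irf3, since a gene moved by breeding carries its neighbours. If it altered the region, genes within 5 Mb of Irf3 would differ more between the infarct libraries than genes elsewhere. In monocyte/macrophage-like cells their median absolute log2 ratio, centred on the median gene, was 0.33 over 61 genes, against a median of 0.30 over 443 windows of as many neighbouring genes, at the 71.1 percentile. This argues against a difference across the region and leaves single genes open. Atf5 and Saa3, less than 5 Mb from Irf3 and chosen after their values were seen, were 3.58-fold (2.33 to 5.70) and 4.53-fold higher (3.64 to 5.68) in these cells of the Irf3-/- library; Saa3 shares end sequence with 164 genes. Without infarct, wild-type cells of this class had Atf5 and Saa3 at 121 and 453 CPM. The Irf3-/- infarct had 44.7 and 206 CPM and the wild-type infarct 12.5 and 45.6 CPM, so the wild-type libraries lay on both sides of it. The library without infarct also differs by infarct, and 177 of its 204 Saa3 UMIs over all cells lay in 3 cells. Atf5 had 591 CPM in its low barcodes. A part of genotype in the difference between the infarct libraries thus stays open. The ratio of Bcl2l12 in monocyte/macrophage-like cells was 0.356 (0.157 to 0.761), from 11 and 23 UMIs, and its log2 ratio there was 0.45 with thinned cells.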
